A study of Mus musculus with 8 samples.

How the data were processed

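RNA from 8 cultures of p53-knockout mouse mesenchymal stem cells, 4 clonal lines with a luciferase or a cFos retrovirus, was the material. Per the labels' protocols, the cells were below passage 20, RNA came from a column kit, and polyadenylated RNA was made into Illumina TruSeq libraries. Per the submitters' processing notes, CASAVA 1.8.2, TopHat and Cufflinks were used with the mouse build mm9. The versions of TopHat and Cufflinks, their options and the annotation release are not given in the sources used here. Per the file headers, each deposited table is a Cufflinks tracking table with 1 entry per RefSeq transcript, holding FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with its confidence limits. Per the file headers, the tables also hold the coverage of each transcript (mean depth per base, a signal that is not normalized) and other columns such as the transcript length. The authors' FPKM values are estimates that split reads between transcripts by a model, so near-identical genes can trade reads, and no scaling between libraries is recorded.

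Each table had 30769 entries with 30239 distinct transcript accessions. Gene symbols came from an NCBI RefSeq table for 30223 entries and from GENCODE M21 metadata of build GRCm38, used for names alone, for 184 more. The 362 entries left under their accession held 0.828% of the mean FPKM. Entries with the same symbol were summed into 23503 genes, of which 4318 had more than 1 entry. Coordinates are those of the deposited tables in mm9, counted from 1. A status other than OK in any library took out 3 genes. Depth was estimated as coverage times length summed over transcripts, 6.93 to 9.14 gigabases per library. The files hold no read counts, so no counting interval was computed for single values.

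The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 0.5), over genes with at least 1 FPKM in at least 4 of the 8 libraries, with Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on that log2 scale, which understates the change of low genes. Fos, Sox9 and Trp53 also had exact two-sided permutation tests over the 70 arrangements of 4 against 4 and the 16 exchanges of arms within clones. Gene lists were tested with camera (correlation preset to 0.01, and estimated) and fry where at least 5 members were tested, with adjustment over 19 lists. Lists covered AP-1, lineages, other cell types, signalling pathways, interferon response, metabolism, the cell cycle, p53 targets and controls, 23 in all. The clone comparison used limma's F test of the clone terms in a model of arm plus clone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots.

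The design, the tests, the lists, the rule for named genes and most alternatives were set before the data were examined. The genes named are Fos, Sox9 and Trp53, the 12 largest rises and 12 largest falls among called genes with the same sign in all 4 clones (predicted, pseudo and small RNA genes passed over), up to 4 members of each list with the smallest adjusted p, and for the clones the 8 genes of smallest adjusted p with a mean of at least 10 FPKM plus up to 2 list members. Other list members are named for their values. Members outside the rule were chosen after their values were seen, such as those that gained a call with the block or when a library was left out.

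The main model had no clone term. The clone numbers pair the libraries, since libraries with the same number come from the same line. Deviations from the arm means correlated within a clone by 0.174, 0.593, 0.349 and 0.437 for clones 2, 4, 8 and 12, and at most by -0.0086 between clones. The deviations of an arm sum to 0, so positive values within clones push those between clones below 0. Only the values within clones bear on the pairing. A fit with the clone as a block was therefore run beside the main one.

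The code was tested on simulated data of the cFos and Luc comparison with 11162 genes. Without the block it recovered 61% of 100 genes changed 2-fold and 92% of 100 changed 4-fold, with 1 false call (0.649% of calls). With the block it recovered 82% and 100%, with 10 false calls (5.21%). The clone test recovered 95.5% of 200 simulated clone genes (SD 2 on the log2 scale), with 0 false calls when no clone effect was simulated. That SD was a chosen value and not the spread of the real clones, so recovery of smaller clone differences was not measured. A list of 10 genes shifted by 1 on the log2 scale passed camera (adjusted p = 3.15e-22; 0.00223 with an estimated correlation) and fry (7.34e-04), and none of the other lists passed. Genes were simulated independently of each other, so this does not show how often the list tests pass falsely when genes are correlated. The estimated correlation reached 0.813 in the real interferon list.

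Alternatives were a pseudocount of 0.1 or 1, no filter, a minimum of 5 FPKM, median-ratio scaling, quantile normalization, the clone block, eBayes without trend or robust, transcripts tested singly, genes with a failed status kept, a 2-fold minimum, and each library or clone left out. Coding transcripts alone, the lists without each library, and the block with an estimated correlation were added after seeing the data. When a library was left out, the genes tested were held at those of all 8 libraries. That choice was made after both versions had been computed: applying the filter again to the 7 libraries left removes genes expressed in 1 arm and gave lower counts between the arms, and both versions are given in the closing section. With transcripts tested singly, limma called 339 rises and 292 falls over 13348 entries. Results of that setting are given as these counts alone, and splicing was not analysed here. Some list members are counted but not reported here by name.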

Results

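Polyadenylated RNA was sequenced from mouse bone marrow-derived mesenchymal stem cells, the stromal progenitors of bone, cartilage and fat, that lack the tumour suppressor p53. The cells came from 4 clonal lines, numbered 2, 4, 8 and 12. Each line received a retrovirus carrying luciferase (Luc), an enzyme that serves as the control, or a retrovirus carrying cFos, the AP-1 transcription factor subunit encoded by Fos. This gave 4 Luc and 4 cFos libraries, 1 of each per clone, and a name such as Luc 8 below stands for the Luc library of clone 8. The sequence aligned to annotated transcripts came to 6.93 to 9.14 gigabases per library, 7.82 ± 0.930 in Luc and 7.88 ± 0.901 in cFos (SD, n = 4). Between 10973 and 11124 genes per library reached 1 FPKM. Group values are mean FPKM ± SD over the 4 clones (n = 4), so the spread is that between clonal lines, and there was no second library of any clone and virus.

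The cFos and Luc libraries separated along the leading principal component, which held 43.6% of the variance, and the clones spread along the next, which held 20.7%. The virus arm took 41.6% of the sum of squares over all tested genes, where noise alone would give 14.3%. The clone took 40.0%, where noise alone would give 42.9%, against 18.4% left over on the same 3 degrees of freedom. Correlations of log2 values were 0.874 to 0.950 between clones of the same arm, 0.856 to 0.921 between the 2 arms of the same clone, and 0.839 to 0.896 between libraries that shared neither. The 10 most abundant transcripts held 7.56 ± 0.135% of the FPKM in Luc and 9.56 ± 1.45% in cFos.

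**Figure D1:**
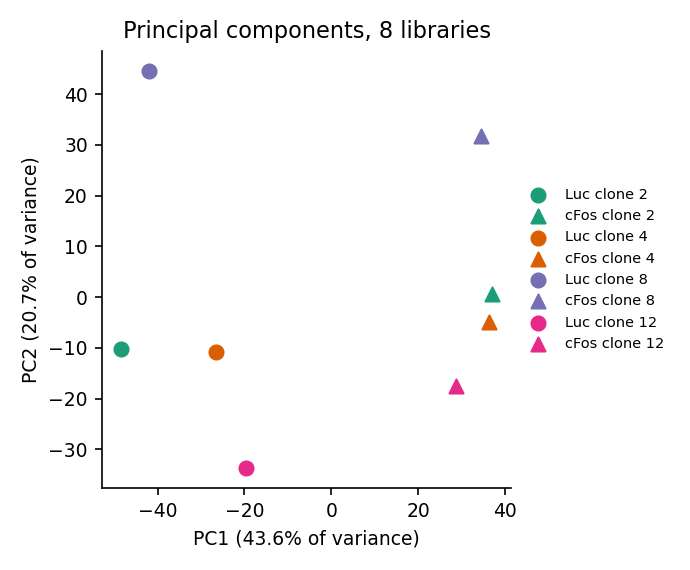
Scores of the 8 libraries on principal components 1 (x axis, 43.6% of the variance) and 2 (y axis, 20.7%), with circles for Luc, triangles for cFos and a colour for each clone. The 4 Luc libraries lie left of 0 on component 1 and the 4 cFos libraries right of it, and clone 8 lies highest on component 2 in both arms.

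The transduced gene was examined in every library. Fos (chromosome 12, 86814851 to 86818219, mm9) rose from 116 ± 125 FPKM in Luc to 697 ± 226 in cFos, a log2 fold change of 3.06 (SE 0.58, limma adjusted p = 0.0184). It was higher in all 4 clones, 7.73-fold in clone 2, 16.4-fold in clone 4, 3.38-fold in clone 8 and 11.6-fold in clone 12. The Luc libraries held 76.2, 41.1, 302 and 43.5 FPKM in clones 2, 4, 8 and 12, and the cFos libraries 589, 675, 1019 and 505. An exact two-sided permutation test gave p = 0.0286 over libraries and 0.125 when arms were exchanged only within clones, the smallest values that 4 against 4 and 4 pairs can give. The limma adjusted p lay above the threshold without Luc 2 (0.0510), cFos 2 (0.0580), cFos 4 (0.0561) or cFos 8 (0.0539), and also with no filter on low genes (0.0540). Whether the transduced cDNA is the mouse sequence is not in the labels, and these values do not part the cell's own transcript from the viral one. Trp53, which encodes p53 (chromosome 11, 69393861 to 69405375), was listed at 7.67 ± 1.30 FPKM in Luc and 6.58 ± 0.246 in cFos, a log2 difference of -0.19 (exact two-sided permutation p = 0.171 over libraries and 0.250 within clones). Which part of Trp53 is deleted is not in the labels, so these transcript levels neither check nor contradict the knockout.

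**Figure D2:**
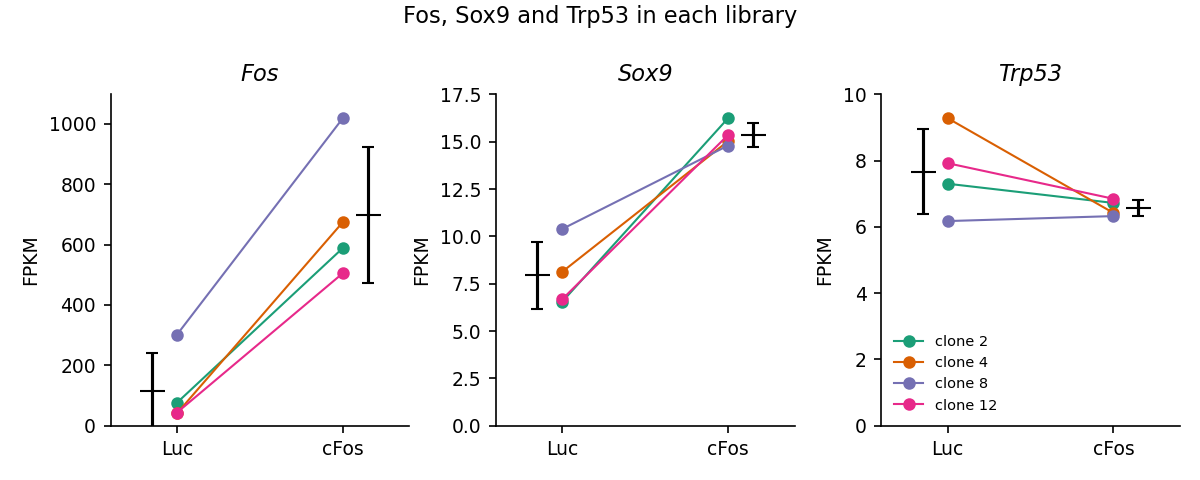
FPKM (y axis, linear from 0) of Fos, Sox9 and Trp53 in Luc and cFos libraries (x axis), with a point per library, a line joining the 2 libraries of a clone, and black marks for the mean ± SD (n = 4), the lower end of the Luc Fos bar being hidden below 0. Fos ran from 41.1 to 302 FPKM in Luc and from 505 to 1019 in cFos.

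Which genes differ between the arms was tested over 11162 genes. In cFos, 326 genes rose and 293 fell, 5.55% of those tested, and 244 of the rises and 197 of the falls were at least 2-fold. The 619 genes had the same direction in all 4 clones, which was so for 36.2% of all tested genes. With the clone as a block, 503 rose and 478 fell, and 313 rises and 267 falls were shared by both fits. Over the same genes, the number of rises was 150 without cFos 2 and 190 without cFos 4. The number of falls was 147 without Luc 2, 85 without cFos 2, 172 without Luc 4, 101 without cFos 4 and 138 without cFos 8. With the filter applied again to the libraries left, the lowest counts were 90 rises and 69 falls, both without cFos 2. Of the 619 genes, 224 kept their call whichever library was left out over the same genes, 146 rises and 78 falls.

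Of the 12 largest rises, L1cam, a neural cell adhesion molecule (chromosome X, 71099119 to 71126173), rose from 0.0711 ± 0.0440 to 19.3 ± 4.43 FPKM (log2 fold change 5.09, SE 0.20, adjusted p = 1.12e-05). Ngef, a guanine nucleotide exchange factor (chromosome 1, 89373404 to 89470445), rose from 0.238 ± 0.164 to 33.9 ± 9.41 (5.52), and Cadm4, another adhesion molecule (chromosome 7, 25267042 to 25289552), from 0.792 ± 0.582 to 47.3 ± 14.2 (5.27). Adam8, a membrane metalloprotease (chromosome 7, 147164840 to 147178387), rose from 0.601 ± 0.568 to 29.2 ± 7.79 (4.84). Ppl, the desmosomal protein periplakin (chromosome 16, 5086384 to 5132574), rose from 1.17 ± 0.630 to 47.7 ± 21.1 (4.80). Sema3e, a secreted semaphorin (chromosome 5, 14025276 to 14256689), rose from 2.91 ± 1.76 to 72.9 ± 19.7 (4.56). Sncg, gamma-synuclein (chromosome 14, 35183460 to 35187855), rose by 4.67 and Baalc (chromosome 15, 38765455 to 38784462) by 4.55. The prolactin family genes Prl2c2 (chromosome 13, 13088391 to 13097597) and Prl2c3 (chromosome 13, 12883088 to 12892346) rose from 10.9 ± 10.2 to 290.0 ± 72.7 and from 7.79 ± 8.32 to 225 ± 98.6, and the split of reads between these near-identical genes is uncertain. Hba-a1, alpha-globin, was listed at 0 in 3 Luc libraries and at 0.0440 FPKM in Luc 4, and reached 69.95 ± 50.7 in cFos (6.87 on the scale of log2 FPKM plus 0.5). Its transcript is listed at separate positions on chromosome 11, 32183672 to 32184486 and 32196489 to 32197303, and the value is their sum. The near-identical Hba-a2 is listed at nearly the same positions, which makes the split between these copies uncertain. Nlrp2, of the NOD-like receptor family (chromosome 7, 5250149 to 5302637), rose from 0.345 ± 0.611 to 41.8 ± 32.3 (5.04, adjusted p = 0.0237). Its call ended without any 1 of Luc 2, cFos 2, Luc 4, cFos 4, Luc 8 or cFos 12, with adjusted p up to 0.0778, while the other 11 held without each library over the same genes.

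The 12 largest falls included Usp18, Isg15 and other genes of the interferon response list. Usp18, which removes the ubiquitin-like protein ISG15 from its targets (chromosome 6, 121195924 to 121220935), fell from 65.9 ± 67.2 to 0.560 ± 0.467 FPKM (log2 fold change -5.51, SE 0.66, adjusted p = 0.00284). Isg15 itself (chromosome 4, 155573533 to 155574927) fell from 284 ± 263 to 6.63 ± 4.15 (-4.99). The oligoadenylate synthetase family genes Oas1a (chromosome 5, 121346266 to 121357534), Oasl2 (chromosome 5, 115346943 to 115362254) and Oas1g (chromosome 5, 121326151 to 121337607) fell by 5.29, fell by 4.69 and fell by 4.10 on the log2 scale, and the split between the close paralogs Oas1a and Oas1g is uncertain. Irf7, a transcription factor of interferon induction (chromosome 7, 148449082 to 148452323), fell from 47.9 ± 47.5 to 1.34 ± 0.292 (-4.23). Bst2, the membrane protein tetherin (chromosome 8, 74058161 to 74061336), fell from 357 ± 298 to 15.6 ± 1.396 (-3.95). Ifi44 (chromosome 3, 151393887 to 151412923), the GTPase gene Iigp1 (chromosome 18, 60535683 to 60552283), Trim30a (chromosome 7, 111557540 to 111613707) and Rtp4 (chromosome 16, 23610005 to 23614308) had log2 fold changes of -4.99, -4.75, -3.97 and -3.95. H2-Q4, a class I histocompatibility gene with close paralogs (chromosome 17, 35516562 to 35521619), fell from 46.8 ± 39.3 to 1.74 ± 0.457 (-3.98). All 12 kept their call without each of the 8 libraries over the same genes, and with the filter applied again Bst2 lost it without cFos 2 (0.0515).

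**Figure D3:**
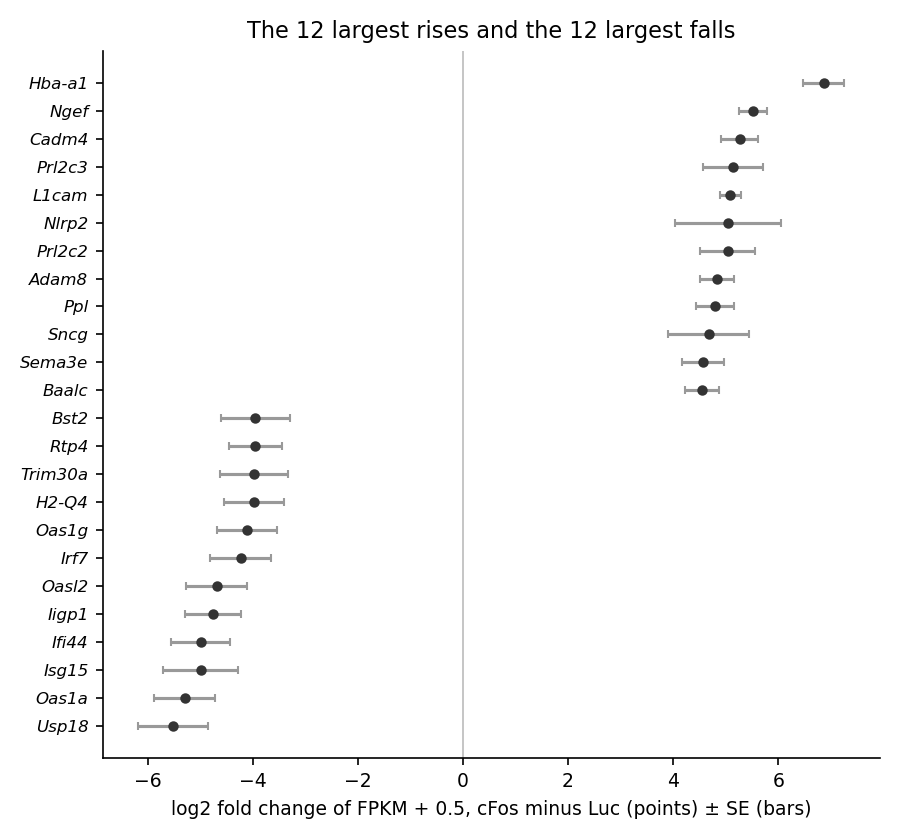
Log2 fold change of FPKM plus 0.5, cFos minus Luc (x axis), for the 12 largest rises and 12 largest falls (y axis), with points for the estimate and bars for ± 1 SE from the limma fit (4 libraries per arm). Values run from -5.51 for Usp18 to 6.87 for Hba-a1, and the bar of Nlrp2 is the widest.

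Interferon response genes were lower in cFos. Of the list's 28 tested genes, 23 fell, none rose and 5 did not pass, and 28 fell when adjusted over the list alone. All 28 were lower in the cFos library of each clone, and the median log2 difference was -4.49 in clone 2, -2.76 in clone 4, -1.94 in clone 8 and -2.23 in clone 12. Irf9, a transcription factor that relays the interferon signal, fell from 31.6 ± 11.3 to 7.24 ± 0.784 FPKM. The list's median was -2.85 (camera adjusted p = 1.37e-24; adjusted p = 0.585 with an estimated correlation of 0.813 between its genes; fry adjusted p = 0.0283, and up to 0.107 without 1 library). Without cFos 2, 14 of the list fell. Of the blood cell markers, Cd14 was the 1 gene expressed enough to be tested, at 1.63 ± 0.759 in Luc and 1.68 ± 0.425 in cFos.

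Sox9, the cartilage transcription factor in the series title, rose from 7.94 ± 1.79 to 15.4 ± 0.635 FPKM (chromosome 11, 112643524 to 112649071), a log2 fold change of 0.93 (SE 0.16, limma adjusted p = 0.0115). The rise was 2.48-fold in clone 2, 1.85-fold in clone 4, 1.42-fold in clone 8 and 2.30-fold in clone 12 (exact two-sided permutation p = 0.0286 over libraries and 0.125 within clones, again the smallest possible). Without cFos 2 its adjusted p was 0.0489, and 0.0594 when the filter on low genes was applied again to the 7 libraries left.

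Few cartilage genes reached the level tested. Of 38 genes of the chondrocyte list in the files, 10 could be tested, of which 2 rose, none fell and 8 did not pass. Besides Sox9 the rise was that of Papss2, which makes the sulfate donor for proteoglycans (10.2 ± 2.83 to 36.3 ± 9.36 FPKM, adjusted p = 0.00451). Adjusted over the list alone, 3 rose and 1 fell, adding Sox5, a partner of Sox9 (2.41 ± 1.24 and 4.27 ± 0.624), and Col10a1, the collagen of hypertrophic cartilage (3.24 ± 1.72 and 0.849 ± 0.650). Over all genes, Col10a1 passed without Luc 12 (0.0381) and Sox5 without Luc 2 (0.0322). Col2a1, the main cartilage collagen, reached 1 FPKM only in Luc 2 and Luc 12, so the filter left it out of the test. It was at 15.7, 0.503, 0.182 and 35.2 FPKM in Luc clones 2, 4, 8 and 12 and 0.217, 0.127, 0.0213 and 0.741 in cFos, lower in cFos in each clone. Acan, the cartilage proteoglycan aggrecan, was at 0.0172 ± 0.0181 in Luc and 0.726 ± 1.28 in cFos. The list did not pass (camera adjusted p = 0.444; adjusted p = 0.717 with an estimated correlation; fry adjusted p = 0.119, and 0.00519 without Luc 8, where camera gave 0.205), and its median was 0.13 and its mean -0.01. These values leave out Col2a1. With no filter, over 38 genes, camera's sign turned from up to down (adjusted p = 0.844).

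Bone genes gave 1 call. Of 18 tested osteoblast genes, 1 fell, none rose and 17 did not pass, with the same count adjusted over the list alone. The fall was Omd, the bone matrix proteoglycan osteomodulin (25.0 ± 18.4 to 4.51 ± 1.70 FPKM, adjusted p = 0.0330). Runx2, the transcription factor of the bone lineage, was at 25.0 ± 3.23 and 20.3 ± 1.60, and Sparc, the matrix protein osteonectin, at 1225 ± 319.8 and 1687 ± 350.2. With the clone as a block 2 fell, Omd and Pdpn (0.0148). The call of Omd ended without Luc 2, cFos 2, Luc 4, cFos 4 or cFos 8 (up to 0.106), and Phex, at 1.04 ± 0.537 and 4.28 ± 2.39, passed without cFos 8 (0.0173). The list did not pass (camera adjusted p = 0.965; adjusted p = 0.984 with an estimated correlation; fry adjusted p = 0.941), with a median of -0.0015 and a mean of -0.19 while camera's sign was up and fry's down.

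Among smooth muscle and myofibroblast genes, of 12 tested, 5 fell, none rose and 7 did not pass, and 9 fell both when adjusted over the list alone and with the clone as a block. The contractile genes Tagln and Myl9, transgelin and a myosin light chain, fell from 452 ± 64.4 to 80.8 ± 53.6 FPKM and from 560.3 ± 142 to 119.6 ± 60.8, and Acta2, smooth muscle actin, from 1216 ± 375 to 289 ± 202. Cald1 and Csrp1 also fell. The list's median was -1.77 (camera adjusted p = 1.93e-06; adjusted p = 0.585 with an estimated correlation; fry adjusted p = 0.0585, and 0.0423 without cFos 12, 0.0278 with no filter and 0.0295 at 5 FPKM). The count was 2 without Luc 2, cFos 2 or cFos 4 and 3 without Luc 12. Calls ended for Acta2 without Luc 2, cFos 2, Luc 4, cFos 4 or Luc 12 (up to 0.0810), for Csrp1 without Luc 2, cFos 2, cFos 4 or cFos 8 (up to 0.103), and for Cald1 without any library but cFos 12 (up to 0.0869).

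Among stromal progenitor genes 1 of 16 rose, 1 fell and 14 did not pass. Cxcl12, the chemokine that retains blood stem cells in marrow, fell from 3364 ± 2679.9 to 359 ± 202 FPKM (log2 fold change -3.07, adjusted p = 0.0154, and 0.0558 without cFos 2). Pdgfrb, a growth factor receptor, rose from 86.8 ± 16.2 to 147 ± 28.6, a call that ended without Luc 2, cFos 2, cFos 4, Luc 8, cFos 8 or Luc 12 (up to 0.129). Adjusted over the list alone 1 rose and 3 fell, and with the clone as a block 2 rose and 4 fell, Mcam (0.0190) among them, while 3 fell without Luc 8 and 2 without Luc 12 or cFos 12 (camera adjusted p = 0.413). Of 16 adipocyte genes Acsl1, which activates fatty acids, rose (16.8 ± 4.05 to 34.5 ± 9.87), none fell and 15 did not pass (camera adjusted p = 0.835). Acsl1 also passed adjusted over the list alone, and lost its call without cFos 2, Luc 4, cFos 4, Luc 8, cFos 8 or Luc 12 (up to 0.130). Pparg, the transcription factor of fat cells, was at 39.6 ± 17.3 and 64.1 ± 26.9. With the clone as a block 2 adipocyte genes rose and 3 fell, Klf15 (0.0415) among them, and without Luc 12 Zfp423 fell (0.0225).

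**Figure D4:**
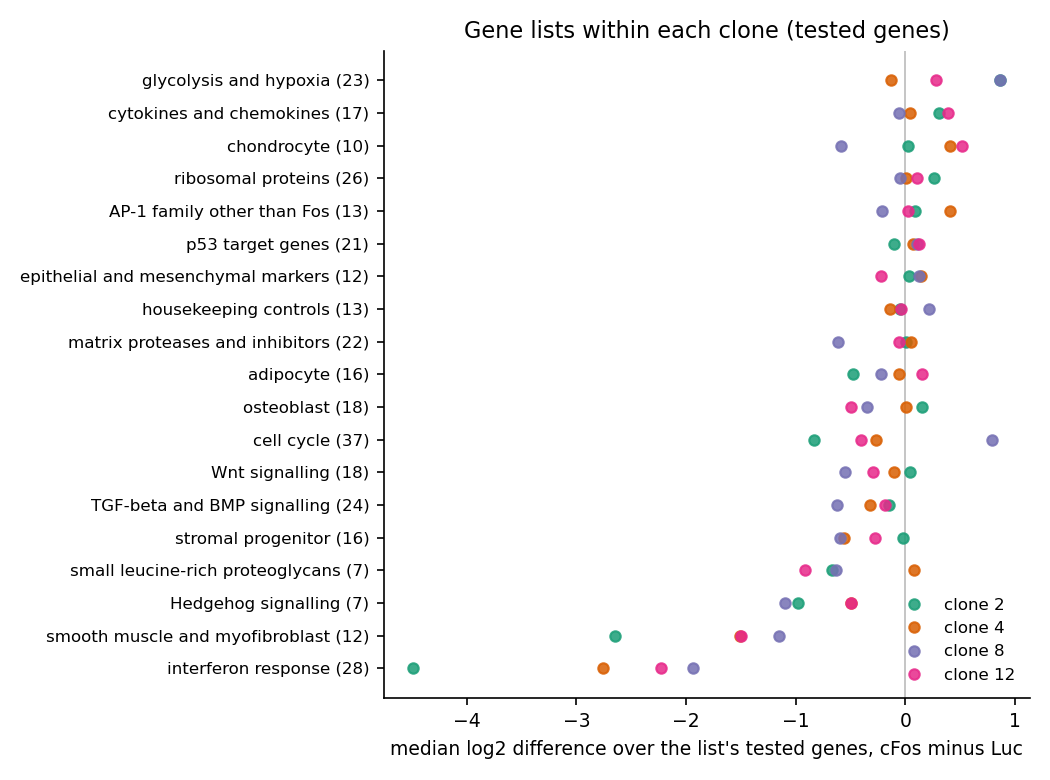
Median log2 difference, cFos minus Luc (x axis), over the tested genes of each gene list (y axis, number of genes in brackets), with a coloured point for each of the 4 clones. The interferon response medians lie from -4.49 to -1.94 and the smooth muscle medians from -2.65 to -1.16, and the cell cycle median is 0.79 in clone 8 and below 0 in the other 3 clones.

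Signalling genes moved in both directions. Of 24 TGF-beta and BMP genes, 2 rose, 2 fell and 20 did not pass (adjusted over the list alone, 2 rose and 3 fell). Tgfb1, the TGF-beta ligand, rose from 10.97 ± 0.735 to 29.0 ± 3.53 FPKM (adjusted p = 8.46e-04), and Tgfbi, a matrix protein that TGF-beta induces, from 31.2 ± 19.2 to 362 ± 129 (log2 fold change 3.62). The BMP targets Id3 and Smad6 fell from 167 ± 14.1 to 99.7 ± 19.0 and from 8.94 ± 0.638 to 4.89 ± 1.61. With the clone as a block 2 rose and 6 fell. Of 18 Wnt genes 2 rose, 2 fell and 14 did not pass, and adjusted over the list alone 2 rose and 3 fell. Notum, a secreted Wnt inhibitor, rose from 0.217 ± 0.141 to 6.42 ± 4.02, and so did Kremen1, a receptor of the Dickkopf Wnt inhibitors (11.1 ± 1.29 to 19.4 ± 2.73). Rspo2, which enhances Wnt signals, fell from 88.3 ± 60.7 to 10.7 ± 5.46, and Nkd2, an inhibitor, from 1.92 ± 0.789 to 0.336 ± 0.344. Neither list passed camera (adjusted p = 0.574 and 0.965). Leaving out 1 library ended the calls of Id3 (Luc 2, Luc 4, cFos 4, Luc 8, cFos 8 or Luc 12, up to 0.0719), Smad6 (any but cFos 8, up to 0.122), Kremen1 (cFos 2, 0.0550) and Nkd2 (any but Luc 8 or cFos 12, up to 0.0990).

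Of 7 Hedgehog genes 2 fell, none rose and 5 did not pass, and 3 fell adjusted over the list alone, with Cdon (11.3 ± 1.43 and 5.95 ± 2.20), which also fell with the clone as a block (0.0406) and without cFos 12 (0.0249). Those over all genes were Smo, the signal transducer (59.7 ± 11.6 to 32.0 ± 5.28 FPKM), and Sufu, an inhibitor of the pathway (12.6 ± 2.62 to 6.74 ± 0.449), which act in opposite ways. The list had a median of -0.84 (camera adjusted p = 0.0124; adjusted p = 0.585 with an estimated correlation; fry adjusted p = 0.0729, and 0.0263 without Luc 4, 0.0295 at 5 FPKM and just under the threshold without cFos 12), and camera gave 0.0708 without Luc 12 and 0.0861 with no filter on low genes. Leaving out 1 library ended the calls of Smo (Luc 2, cFos 2, cFos 4 or cFos 12, up to 0.0713) and Sufu (Luc 2, cFos 2, cFos 4 or cFos 8, up to 0.0711).

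Among 17 cytokine and chemokine genes 2 rose, 2 fell and 13 did not pass. Hgf, hepatocyte growth factor, fell from 18.8 ± 8.90 to 1.89 ± 0.722 FPKM (log2 fold change -2.95, adjusted p = 0.00254), and Cxcl1, a neutrophil chemokine, from 45.1 ± 18.2 to 19.3 ± 6.06. Il34, a ligand of the macrophage growth factor receptor, rose from 2.03 ± 1.20 to 8.21 ± 2.39 and Hbegf, an EGF receptor ligand, from 3.72 ± 1.91 to 11.1 ± 3.50. Adjusted over the list alone 4 rose and 4 fell, and with the clone as a block 4 rose and 2 fell (camera adjusted p = 0.759). Leaving out 1 library ended the calls of Il34 (cFos 2 or cFos 4, up to 0.0618), Hbegf (any but Luc 12, up to 0.114) and Cxcl1 (any but cFos 12, up to 0.145).

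Of 22 matrix protease and inhibitor genes 3 rose, none fell and 19 did not pass (adjusted over the list alone 4 rose and 4 fell, camera adjusted p = 0.835). Mmp15, a membrane metalloprotease, rose from 0.956 ± 0.738 to 9.95 ± 4.13 FPKM, and Plaur, the urokinase receptor, from 9.90 ± 3.75 to 27.0 ± 4.62. Of 7 small leucine-rich proteoglycans 2 fell, none rose and 5 did not pass (3 fell adjusted over the list alone, camera adjusted p = 0.213, and 0.0247 over genes of at least 5 FPKM, where it was 0.358 with an estimated correlation and 0.0295 by fry; in clone 4 only 3 of the 7 were lower in cFos). Ogn, osteoglycin, fell from 383 ± 90.7 to 126 ± 51.1, and the other fall was Omd, counted above among the bone genes with the libraries its call rests on. Of 12 epithelial and mesenchymal markers 3 rose, none fell and 9 did not pass, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.213; at 5 FPKM fry gave 0.0291 and camera 0.105). Vim, the mesenchymal filament vimentin, rose from 1481 ± 362 to 4893 ± 1394, Zeb1, a repressor of epithelial genes, from 12.4 ± 1.54 to 27.0 ± 4.76, and the epithelial keratin gene Krt19 from 10.8 ± 12.2 to 147 ± 149. With the clone as a block Krt19 did not pass (0.0508), and Snai2 fell (0.0243). Leaving out 1 library ended the calls of Plaur (cFos 2 or cFos 4, up to 0.0569) and Krt19 (any but Luc 4, up to 0.126), and without Luc 12 the proteases had 4 rises and 1 fall.

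Of 13 AP-1 genes other than Fos, 1 rose, none fell and 12 did not pass, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.755 with an upward sign, against a median of -0.07 and a mean of -0.0057). Fosl1, a close relative of Fos, rose from 3.12 ± 1.36 to 9.77 ± 3.38 FPKM (adjusted p = 0.0417), a call lost with the clone as a block (0.0663) and without Luc 2, cFos 2, Luc 4, cFos 4, Luc 8 or cFos 8 (up to 0.121). With that block Fosl2 rose (41.4 ± 12.4 to 63.4 ± 12.0, 0.0269), and Jun (38.4 ± 13.1 to 23.0 ± 4.55, 0.0403) and Fosb (15.2 ± 16.9 to 3.48 ± 3.56, 0.00820) fell.

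Glycolysis and hypoxia genes had no single call among 23, over all genes or adjusted over the list alone (limma, 11 higher at an unadjusted p under 0.05). Eno2 was at 3.14 ± 0.708 FPKM in Luc and 7.06 ± 3.06 in cFos, and Aldoa at 359 ± 126 and 613 ± 135. The list's median was 0.60 (camera adjusted p = 4.67e-04; adjusted p = 0.717 with an estimated correlation; fry adjusted p = 0.241). By clone the median was 0.87 in clone 2, 0.86 in clone 8 and 0.28 in clone 12, but -0.13 in clone 4, where 13 of the 23 genes were lower in cFos. With the clone as a block Ero1a rose (0.0171), 1 gene rose without Luc 8, and Pfkp rose without Luc 12 (0.0437).

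None of the 37 cell cycle genes passed (camera adjusted p = 0.444; 0.984 with an estimated correlation; fry adjusted p = 0.941), nor did any adjusted over the list alone (1 lower at an unadjusted p under 0.05 by limma). Mcm4, a subunit of the replicative helicase, was at 50.9 ± 10.2 FPKM in Luc and 32.6 ± 4.75 in cFos. Without Luc 8 the list passed with a downward sign by camera at its preset correlation (adjusted p = 4.02e-05) but not with an estimated one (0.696) or by fry (0.155), with falls of Mcm3 (0.0401) and Mcm5 (0.0387). Of 21 p53 target genes 1 fell, none rose and 20 did not pass (camera adjusted p = 0.755). The fall was Fas, a death receptor (4.50 ± 1.90 to 1.29 ± 0.455), which also passed adjusted over the list alone and ended without Luc 2, cFos 2 or cFos 4 (up to 0.0791). Cdkn1a, the cell cycle inhibitor p21, was at 1.95 ± 1.59 and 8.59 ± 5.44 and rose with the clone as a block (0.00228), and Sesn1 fell without Luc 8 (0.0343) or Luc 12 (0.0416). Of the 26 ribosomal protein genes none passed (0 at an unadjusted p under 0.05 by limma, camera adjusted p = 0.213). Of 13 housekeeping controls B2m, the light chain of class I histocompatibility molecules, fell from 2275 ± 1055 to 689.8 ± 146, none rose and 12 did not pass (camera adjusted p = 0.965). B2m also passed adjusted over the list alone, its call ended without cFos 2, Luc 4, cFos 4, cFos 8 or cFos 12 (up to 0.0660), and Actb fell without Luc 8 (0.0432).

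In all, 19 lists were tested together, and 4 of the 17 lists other than chondrocyte and osteoblast passed camera with a preset correlation. With an estimated correlation camera called 0 of the 17 (1 at an unadjusted p under 0.05), and fry called 1, the interferon list (5 unadjusted). The p of fry asks whether a list's genes move on balance in 1 direction, and its mixed p whether they change in either direction. The mixed p passed for every list but osteoblast, adipocyte, cell cycle and ribosomal genes, and was smallest for Wnt signalling (adjusted p = 2.82e-06) and for TGF-beta and BMP signalling and cytokines (5.21e-06 each). Neither compares a list with other genes.

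Few markers of osteoclasts, endothelium, skeletal muscle and blood cells reached the level tested, 4 of 11, 1 of 14, 1 of 15 and 1 of 18. Of the osteoclast markers, Atp6v0d2, a proton pump subunit, rose from 0.108 ± 0.124 to 14.3 ± 8.95 FPKM (adjusted p = 8.46e-04) and Nfatc1, an osteoclast transcription factor also active elsewhere, from 8.77 ± 2.66 to 23.7 ± 2.19 (0.00605). Others of that list were Ctsk at 23.6 ± 29.8 and 14.5 ± 12.0, Itgb3 at 3.10 ± 0.559 and 3.83 ± 2.13, and Oscar at 0.0624 ± 0.0451 and 0.0561 ± 0.0394. Egfl7, the 1 endothelial marker tested, was at 4.74 ± 2.21 and 6.24 ± 1.39, and Acta1, the 1 skeletal muscle marker tested, at 2.02 ± 1.45 and 0.83 ± 0.494. With fewer than 5 tested members the 4 lists had no set test. With no filter on low genes the osteoclast list passed upward by camera (adjusted p = 0.0487) and fry (0.00457) but not with an estimated correlation (0.433), and the other 3 passed by none of these.

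How far the clones differ beside the virus was tested with both in 1 model. By limma's F test 54 of 11162 genes differed among clones, and in the same model 24 of them were also called between the arms, 11 higher and 13 lower in cFos, against 0 in the fit without the clone. Rarres2, which encodes the adipokine chemerin (chromosome 6, 48519697 to 48522669), was at 27.8, 4.47, 88.5 and 0.633 FPKM in Luc clones 2, 4, 8 and 12 and at 12.0, 1.55, 28.7 and 0.498 in cFos (adjusted p = 0.0314). Adipoq, the fat cell hormone adiponectin, was at 25.5, 0.881, 111 and 0.937 in Luc and 3.47, 0.363, 35.2 and 0.275 in cFos, and Plin4, a lipid droplet protein, was at 113 and 249.6 in clone 8 and 14.7 and 27.6 in clone 12. Dpysl3, a cytoskeletal protein of growing neurons, and Itm2a were highest in clone 12, at 78.5 and 27.3 and at 250.4 and 108 in Luc and cFos, and lowest in clone 8, at 0.623 and 0.422 and at 4.39 and 0.491. Tbx15, a transcription factor of skeletal development, was at 61.6 and 55.3 in clone 12 and 13.1 and 9.97 in clone 8. Mgst3 and Arhgap29 were highest in clone 8, and Sfrp4, a secreted Wnt antagonist, and Prelp, a matrix proteoglycan, were among the other list members that differed. The count was 27 without clone 2, 28 without clone 8 and 0 without clone 12 (1549 genes at an unadjusted p under 0.05, against 1839 with all clones). It was also 0 with no filter on low genes (2591 unadjusted) and 6 over genes of at least 5 FPKM.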

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

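The tests of leukocytes, single clones, single libraries, scaling and contractile cells, and that of the virus, were chosen only after the results were seen; those of erythroid cells and shared globin reads were set after the rise of Hba-a1 was seen but before the values they measure. Splits of the libraries for the interferon, smooth muscle, Hedgehog and glycolysis lists were added once the list results were known.

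In 14 of 218 groups of 4 libraries (6.42%) 1 library lay far from the other 3, where chance alone gives about 1 in 20. Fos was at 302 FPKM in Luc 8 against 41.1 to 76.2 in the other Luc libraries. Hba-a1 was at 0.0440 in Luc 4 and listed at 0 in the others, and Ngef at 19.9 in cFos 12 against 37.4 to 39.9. Prl2c3 was at 20.2 in Luc 4 against 2.12 to 4.73, and at 373 in cFos 4 against 166 to 182. In Luc 12, Nlrp2 was at 1.26 against 0 to 0.0904, Adam8 at 1.45 against 0.262 to 0.394, and Sncg at 6.43 against 0.0942 to 0.518. Ppl was at 2.10 in Luc 4 against 0.734 to 0.952, and Ifi44 at 1.18 in cFos 12 against 0.105 to 0.255. Of the helicase genes, Mcm4 was at 66.2 in Luc 2 against 45.1 to 46.7, Mcm3 at 19.6 in cFos 2 against 26.4 to 27.3, and Mcm5 at 14.4 in Luc 8 against 35.8 to 39.9. Pfkp was at 17.8 in cFos 12 against 13.1 to 13.7.

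The lower interferon response genes in cFos were weighed. The tables argue against leukocytes in the Luc cultures, since the highest blood cell marker, Cd14, had a mean of 1.63 FPKM there. They also argue against a direction set by 1 clone, since at least 28 of 28 genes were lower in every clone. The size was uneven, with a list median of -4.49 in clone 2 against -2.76 to -1.94 in the others. Without cFos 2 the list had 14 falls, against 23 with all libraries. Scaling is argued against as well, with a list median of -2.79 under the scaling that moved it most toward 0. It stays open whether the luciferase virus raised these genes in place of cFos lowering them, as 0 libraries of cells with no virus were analysed here. An effect of cFos may account for the difference, as an untested hypothesis.

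The rise of Hba-a1 in cFos was weighed next. Erythroid cells are argued against, since the erythroid markers together came to 3.36% of the Hba-a1 level, and so is a single library, since the lowest cFos library had 33.1 FPKM. Hba-a2 was listed at 3.35% of Hba-a1, below the 10% set beforehand as arguing against shared reads. That bound was wrong, because both transcripts are listed at both gene positions and 42.3% of the Hba-a1 value stands at the second of them, so which copy the reads came from cannot be told apart. Expression of alpha-globin from either copy in cFos cells may explain the values.

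For the lower smooth muscle genes, scaling is argued against (list median -1.71 under the scaling that moved it most toward 0). So is a direction set by 1 clone, since at least 9 of 12 genes were lower in every clone. Fewer contractile cells in the cFos cultures could also lower these genes. With 1 member of the list, Smtn, above -0.2 on the log2 scale, the values do not part that from lower expression in each cell. An effect of cFos may account for them, untested.

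Other splits of the 8 libraries into 4 and 4, 35 with the real one, were compared with the real split. Over the 35, 1 split, the real one, gave as many calls (619, against at most 6 in the others). The models of the other splits had no arm term. Some or all of the arm difference, 41.6% of the sum of squares, therefore stayed in their residual spread. That lowers their calls in any case, so their few calls do not measure chance. The list p values of the other splits come from models of the same form. For the interferon list, 1 split reached its camera p (7.23e-26, against 3.07e-16 at best in the others). The libraries are paired by clone, however, and most of the 35 splits do not part every pair. The interferon splits were also added once the list results were known, with no allowance for the other lists tried. Among the 8 splits that part all 4 pairs the real one also led in both (at most 0 genes and 1.77e-13 at best in the others). But 8 splits are too few for a share under 0.05, so splits that keep the pairing cannot exclude chance for either. Chance cannot be excluded for the chondrocyte list (11 splits as small, 0.234 against 0.0289), the osteoblast list (34 splits, 0.953 against 4.22e-06), the smooth muscle list (2 splits, 2.03e-07 against 1.27e-07), the Hedgehog list (8 splits, 0.00261 against 6.33e-06) or the glycolysis list (11 splits, 7.38e-05 against 7.53e-11). Nor can it for the number of other lists called (17 splits, 4 against at most 7). The split with the smaller p for smooth muscle grouped Luc 2, Luc 4 and Luc 12 with cFos 12. It kept part of the arm difference, so its p does not measure chance alone.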

How the results depend on the processing

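The protein-coding fit, the lists without each library, estimated correlation and fry in these and with other filters, the block with an estimated correlation and the filter applied again were chosen after seeing the data. No result changed its direction while called. Of 62 named or listed genes called, all 62 kept their direction under up to 29 alternatives, 34 kept their call under each of them, and 28 lost it at least once. With the clone block to use the pairing, 503 genes rose and 478 fell, 602 rose and 412 fell with median-ratio scaling added, and 507 rose and 470 fell with a pseudocount of 1; the self-test also recovered more genes with the block, and the cause was not tested further. Apart from the changes given with the results, the block changed no other call of the genes and lists named by the rule. Without the block 391 rose and 255 fell under median-ratio scaling, and 381 and 274 under quantile normalization. With no filter, over 18753 genes, 286 rose and 175 fell. There Fos, at 3.06, had a limma adjusted p of 0.0540, and why it was higher was not tested. That setting also ended the calls of Nlrp2, Vim, Acta2, Cald1, Omd, Pdgfrb, Acsl1, Fosl1, Hbegf, Cxcl1, Krt19, B2m, Fas, Smad6, Nkd2 and the Hedgehog list. Of these, Cxcl1 also lost its call with a pseudocount of 0.1, either scaling, the block with median-ratio scaling, or eBayes without trend, Smad6 with either scaling, Krt19 with a pseudocount of 0.1 or either eBayes setting, and Acsl1 and Pdgfrb without trend. Of the other lists, an estimated correlation called 0, with or without the block (1 and 0 at an unadjusted p under 0.05 by camera), and fry called 1. For the clones, limma called 0 with no filter and 6 at 5 FPKM, and the cause was not tested.

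Leaving out 1 library or clone means fewer samples. It gave 150 to 319 rises, 85 to 295 falls, a Fos log2 fold change of 2.74 to 3.70 and a Sox9 value of 0.85 to 1.06, and for whole clones 204 to 441 rises and 162 to 430 falls with the block and 0 to 38 clone genes. With the filter applied again there were 90 to 318 rises and 69 to 261 falls, with the block 134 to 364 and 117 to 384, and 0 to 41 clone genes, and Sox9 lost its call without cFos 2 (adjusted p = 0.0594), so whether Sox9 holds without that library depends on the choice. Only with it did Bst2, Ogn and Id3 also lose theirs without cFos 2, Rspo2 and Kremen1 without cFos 4, and Acta2, Cxcl12, Kremen1 and Plaur without cFos 8, and genes too low in 1 arm, such as L1cam in Luc, were not tested without a library of the other. Fos and Sox9 kept the same ranges. Without counts, the depth limits low genes in a way that could not be computed.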

Other observations

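The families, the responses of single clones, the interferon receptors and the direction of cell cycle genes by clone were examined only after the results were seen. Genes were grouped by the stem of their symbol, and 358 families with at least 5 tested members were tested for an excess of called genes (one-sided hypergeometric test, adjusted over both directions). Among rises, 6 of 9 Serpinb genes, which encode intracellular protease inhibitors, were called (adjusted p = 3.31e-05), as were 5 of 10 annexins (0.00110), 6 of 22 collagens (0.00426; Col15a1, Col18a1, Col4a5, Col4a6, Col5a3 and Col6a3) and 4 of 9 S100a genes (0.00956). S100a4, a calcium-binding protein, rose from 306 ± 251 to 5647 ± 2613 FPKM (log2 fold change 4.54, higher in all 4 clones). Among falls, 6 of 13 H2 histocompatibility genes were called (1.64e-04), 5 of 12 Parp genes (0.00147, while Parp16 rose), 3 of 5 Cxcl chemokines (0.0154) and 3 of 5 Slfn genes (0.0154). Whether these falls are separate from that of the interferon list was not tested. Under median-ratio scaling and quantile normalization the directions stayed, with 8 Serpinb and 6 annexin rises under each, but with 2 falls the Cxcl family was no longer called (0.274 and 0.292), and under quantile normalization Trim was, with 6 of 31 falling (0.0109; 0.0930 without it). Members of a family can share reads, so their calls are not independent.

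Of the interferon receptors and regulators outside the list, Ifngr1, a receptor subunit for interferon gamma, fell from 79.7 ± 33.1 to 30.7 ± 4.76 FPKM (limma adjusted p = 0.0282), a call lost without cFos 2, cFos 4, Luc 8 or cFos 12 (up to 0.0888). Ifnar1, a receptor subunit for type I interferon, was at 13.6 ± 2.95 and 10.97 ± 0.864.

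The direction of the cell cycle list differed by clone. In clone 8, 36 of its 37 genes were higher in the cFos library, while 35, 33 and 35 were lower in clones 2, 4 and 12. The difference was not tested, since each clone has 1 library per arm. For the same reason the values do not part another response of clone 8 from a trait of the Luc 8 library alone. Among genes called with the block in the other 3 clones, the slope of a clone's log2 differences on those of the others was 1.17 for clone 2, 0.94 for clone 4, 0.88 for clone 8 and 0.65 for clone 12, and 98.7%, 99.5%, 89.9% and 95.3% had the same direction. The genes numbered 383, 384, 871 and 758, so each clone was measured on a different set. Choosing genes by their calls in the other clones tends to overstate the differences there. The slopes and shares therefore do not rank the clones.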
